A study of Mus musculus with 5 samples.

How the data were processed

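The 5 conditions of a mouse embryonic stem cell line were compared, with 1 droplet single-cell RNA library each, and conditions were taken from the sample labels. The values are raw UMI counts per gene and barcode, as deposited; the authors made them with Cell Ranger 6.0.1, per the file headers. Cell Ranger 6.0.1, Seurat 4.1.1, R 4.1.2 and the mm10 build are also named in the submitters' processing notes, without their roles. The labels' extraction protocol names a Trizol lysis and a Lexogen 3' library kit, whereas the matrices are droplet barcode matrices, and which steps apply to these libraries was not settled. The aligner settings, the annotation, the use of strand and the rule by which barcodes were chosen are not given in the sources used here. Without a stated use of strand, genes that overlap or lie antisense to one another, and genes with near-identical copies (histone genes, ferritin light chain, and the Zscan4, Tcstv and Usp17l families), are uncertain.

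Each matrix listed 32285 genes and 10000 barcodes. The ratio of the highest to the lowest UMI count of a barcode was 3.18 in NS, 3.05 in ND and 2.93, 3.31 and 2.93 at 200, 250 and 300 mM sorbitol, so each library is a narrow slice of depths. Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, which left 10000 in NS, 9240 in ND and 9985, 10000 and 9849 in the sorbitol libraries; the filter on genes removed the 760 left out in ND and the 15 and 151 left out at 200 and 300 mM. No doublet caller was run, and leaving out the 5% of kept barcodes with most UMIs was an alternative. No feature for the fluorescent reporter was among the genes, so the reporter itself was not analysed here. Gene coordinates come from GENCODE M21 (GRCm38, the mm10 build), 1-based.

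UMIs were summed over kept barcodes and scaled to CPM. Ratios are log2 ratios of CPM, with exact conditional binomial 95% intervals; levels have exact Poisson intervals and shares exact binomial (Clopper-Pearson) ones. All cover counting error only. A count under 3 UMIs was set to a floor of 3 UMIs, which makes its ratio a bound. No ratio is given where both counts are at or below 3, or where the bound at the floor points away from the difference; this last rule was set after the values were seen, and it changes no value under the settings reported first. Genes were named by a fixed rule: the 10 highest and 10 lowest ratios among genes with at least 50 CPM in either library, leaving out mitochondrial, ribosomal protein and unnamed gene models, plus Zfp42, Nanog, Pou5f1 and Sox2, and up to 4 members with the largest absolute ratio per gene list. For sorbitol against NS, genes had to lie on the same side of NS at all 3 doses and were ranked by the smallest ratio, and list members were those at 300 mM. The mitochondrial and ribosomal protein lists were described as lists.

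The 29 gene lists covered naive, core and formative pluripotency, LIF and STAT3 responsive genes, primitive streak and mesoderm, neuroectoderm, definitive endoderm, primitive and extraembryonic endoderm, trophoblast, a cleavage-stage-like (Zscan4 and Tcstv) state, hyperosmotic response, ATF4 and integrated stress response, endoplasmic reticulum chaperones, heat shock, p53 targets, immediate early genes, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, S phase, G2 and M phase, cholesterol biosynthesis, interferon, germline, imprinted, epithelial, mesenchymal, fibroblast and ribosomal protein genes. Some genes stand in more than 1 list. Members with at least 5 CPM in either library counted as higher or lower at 1.5-fold, and each list's median was set against 10000 random lists of the same size matched on mean expression. One listed symbol, Zscan4a, was not found. The lists, the naming rule, the markers and the alternatives were fixed before the data were examined.

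For single barcodes, UMIs were thinned to 500 per barcode, which every kept barcode reached. One-profile expectations for marker sets came from 20 sets simulated from the library's summed profile. Those for single genes were computed from that profile with the binomial formula. Dispersion is the variance over barcodes relative to that profile, for genes with a mean of at least 0.02 UMIs. Clustering used 3000 barcodes per library, 2000 variable genes, 20 principal components, 15 nearest neighbours and Leiden resolution 0.5. A cluster would have been named from at least 3 detected markers fixed beforehand, with none against the name among its leading genes; no name was given here, because the 3 largest clusters may be the libraries and the smallest had none of the markers among its 10 leading genes. Likeness of ratios was set beside unchanged libraries simulated from the NS profile, with 1 simulated control shared by both ratios, and beside NS barcodes split at random.

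On simulated counts with 200 genes changed 2-fold, 98.5% (ND against NS, 9794 genes), 99.0% (300 mM against NS, 9794 genes) and 98.0% (300 mM against ND, 9767 genes) of the changed genes passed 1.5-fold at a minimum of 5 CPM. Among unchanged genes 0.29%, 0.26% and 0.82% passed, and the intervals covered the true ratio for 95.5%, 95.5% and 95.4% of genes. A simulated library of 1 profile gave a dispersion of 0.995 over 4013 genes. A simulated gene at 0.44 UMIs, lacking in 20% of barcodes, gave 1.12.

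Alternatives were no barcode filter, at least 1000 genes per barcode, at most 10% mitochondrial UMIs, the 5% of barcodes with most UMIs left out, median-of-ratios scaling, CPM outside mitochondrial and ribosomal protein genes, equal weight for each barcode, a 2-fold limit, other CPM minimums, other thinning depths, split NS barcodes and Leiden resolution 1.0. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.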

Results

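Single-cell RNA sequencing was carried out on REX-1 RFP cells, a mouse embryonic stem cell line in which the promoter of Rex1 (gene symbol Zfp42, a marker of the naive pluripotent state) drives a red fluorescent protein. The cells were kept for 72 h in 1 of 5 conditions, with 1 library each. The library named NS was grown with leukaemia inhibitory factor (LIF), the cytokine that maintains mouse embryonic stem cells undifferentiated, and the library named ND without it. The other libraries were grown with LIF and sorbitol, a sugar alcohol that raises the osmolarity of the medium, at 200, 250 and 300 mM. The labels do not spell out the names NS and ND. Each library held 10000 barcodes, with total unique molecular identifier (UMI) counts of 22158653 in NS, 8483612 in ND and 9230639, 9766705 and 8404105 at 200, 250 and 300 mM sorbitol. The median barcode held 2135 UMIs in NS, 818 in ND and 887, 939 and 800 in the sorbitol libraries. Levels are CPM, UMIs summed over the kept barcodes and scaled to the library's total, and ranges in brackets are 95% intervals that cover counting error only. The series has single replicates, so no p-values are given, each ratio compares these libraries and not the conditions, and batch and condition cannot be told apart.

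The reporter gene was read first. Zfp42 (ENSMUSG00000051176; mm10 chromosome 8, 43295063 to 43306980) stood at 562 CPM (552 to 572) in NS and at nearly the same level in ND, 524 CPM (508 to 540). It was 521 CPM (506 to 536) at 200 mM sorbitol, then 778 (761 to 796) at 250 mM and 879 (859 to 900) at 300 mM, which is 1.38-fold and 1.57-fold the NS level. Nanog (ENSMUSG00000012396; chromosome 6, 122707489 to 122714633), a transcription factor of naive pluripotency, was higher in ND than in NS (185 against 123 CPM; log2 ratio 0.58, 0.49 to 0.68) and stood at 124, 169 and 133 CPM over the sorbitol doses. Pou5f1 (ENSMUSG00000024406; chromosome 17, 35506018 to 35510772), which encodes the pluripotency factor Oct4, was level in ND and NS (249 and 248 CPM), close to NS at 250 mM (240.0 CPM; log2 -0.05, -0.12 to 0.02) and lower at 200 mM (185 CPM; log2 -0.42, -0.50 to -0.34) and 300 mM (170 CPM; log2 -0.54, -0.63 to -0.46). Sox2 (ENSMUSG00000074637; chromosome 3, 34650405 to 34652461), its partner factor, was 358 CPM in NS, 514 in ND and 630, 674 and 682 over the doses. The Nanog log2 ratio at 300 mM, 0.11, turned to -0.15 with median-of-ratios scaling. Under that scaling the Zfp42 log2 ratios to NS were -0.33, 0.23 and 0.39 at 200, 250 and 300 mM. It shifted all ratios at 250 mM by -0.24, which takes Pou5f1 there below the interval given. Among barcodes with at least 1000 genes, of which ND kept 8 and the 200 mM library 22, the log2 ratio of Zfp42 at 200 mM turned from -0.11 to 0.17 (-0.43 to 0.71), that of Pou5f1 at 200 mM from -0.42 to 0.07 and that of Sox2 in ND from 0.52 to -0.17.

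**Figure D1:**
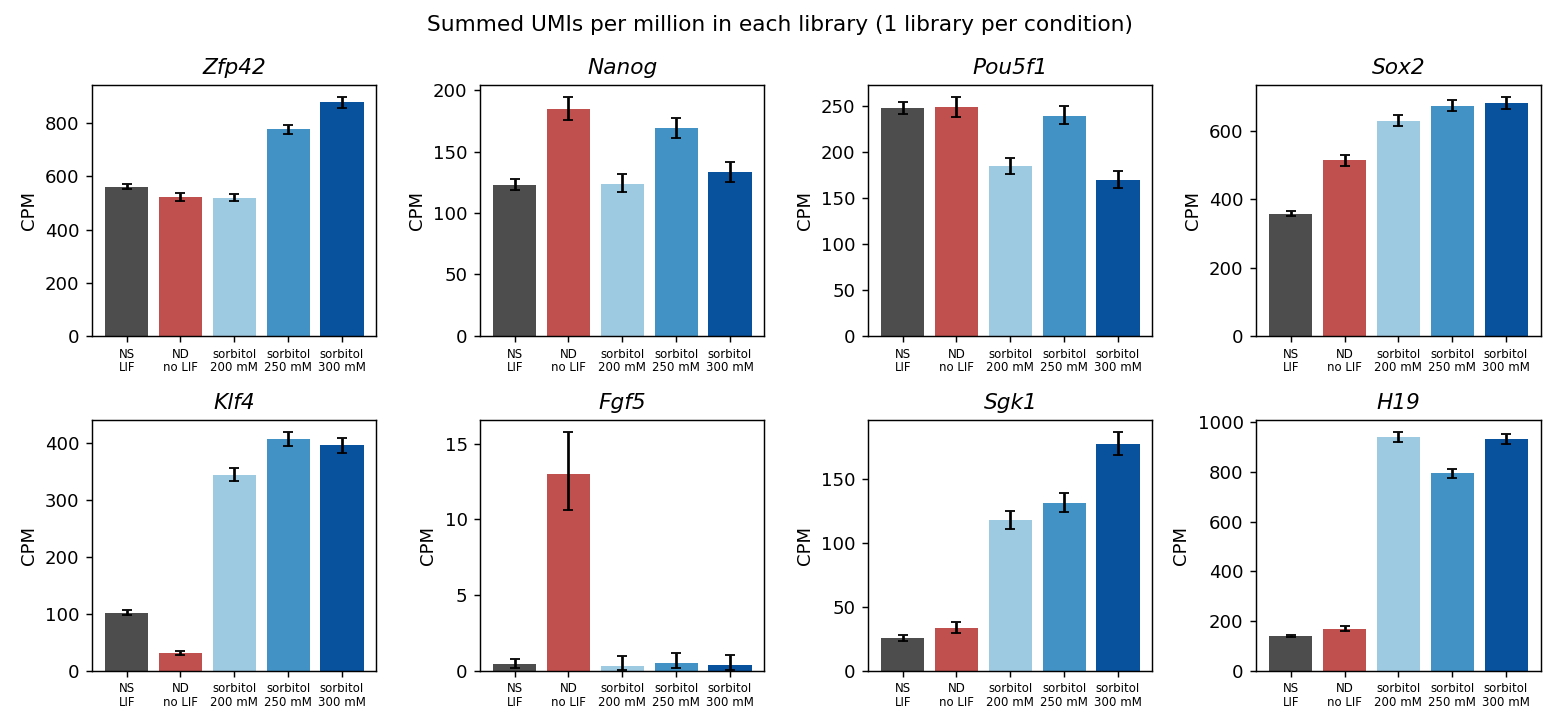
Bars give CPM of 8 genes in each of the 5 libraries, with 95% Poisson intervals for counting error. Zfp42 is higher at 250 and 300 mM sorbitol (778 and 879 CPM) than in NS (562 CPM), Klf4 is lowest in ND (30.9 CPM), Fgf5 is near 0 outside ND (13.0 CPM), and Sgk1 and H19 are higher at all 3 sorbitol doses.

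The comparison of ND with NS sets 72 h without LIF against 72 h with it. Without LIF, 6 of 10 measured LIF and STAT3 responsive genes were lower, and 9 of 12 genes of the formative and primed list, which covers the step after naive pluripotency, were higher. Socs3, the feedback inhibitor of LIF signalling, was 9.95-fold lower (36.5 CPM in NS, 3.67 in ND; log2 -3.32, -3.90 to -2.78). Fgf5, the growth factor gene that marks the post-implantation epiblast, went from 0.41 to 13.0 CPM, 32.1-fold (4.02 to 6.17 on the log2 scale), and Lef1, a transcription factor of the Wnt pathway, from 3.70 to 41.9 CPM (log2 3.50, 3.15 to 3.87). Zfp42 itself and the other general markers above did not follow Klf4 and Tbx3, naive factors induced by LIF, which were 3.31-fold and 3.55-fold lower.

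Of genes with at least 50 CPM in either library, those highest in ND relative to NS were Trim2 (14.0 to 56.0 CPM, 3.99-fold), Ccnd1, which encodes cyclin D1 (29.1 to 113 CPM, 3.88-fold), and Otx2, a formative transcription factor (21.5 to 78.8 CPM, 3.66-fold). Adam19, Pdzd4, Id3, Sesn3, Mest, Col18a1 and Emb followed with folds from 3.47 down to 2.83. Ccnd1 lies on chromosome 7 (ENSMUSG00000070348, 144929931 to 144939925) and Otx2 on chromosome 14 (ENSMUSG00000021848, 48657677 to 48673819). The lowest were Cyp2s1 (59.3 to 11.8 CPM, 5.04-fold lower), the keratin gene Krt19 (81.3 to 16.9 CPM, 4.80-fold lower) and Pcolce (4.26-fold lower). S100a6, a calcium-binding protein gene, was lower by 3.68-fold (265 to 72.0 CPM), Anxa2 by 3.55-fold (147 to 41.5 CPM) and Ndufa4l2 by 3.22-fold (138 to 43.0 CPM), with Dhrs7 at 3.20-fold. Hist1h2ap (3.23-fold lower) shares near-identical copies with other histone genes, so its level is uncertain. Klf4 (ENSMUSG00000003032) lies on chromosome 4 from 55527143 to 55532466 and Tbx3 (ENSMUSG00000018604) on chromosome 5 from 119670669 to 119684724.

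In the fixed gene lists, a member counted as higher or lower at 1.5-fold. Of 10 measured LIF and STAT3 responsive genes, 6 were lower in ND and 1 higher (median log2 -0.99, below all of 10000 random lists matched on expression), led by Socs3, Bcl3 (-2.25), Klf4 (-1.73) and Icam1 (-1.25). Of 12 formative and primed genes, 9 were higher and 1 lower (median 1.21), led by Fgf5, Lef1, Otx2 (1.87) and Pou3f1 (1.86). The 20 naive pluripotency genes split, with 5 lower and 3 higher (median -0.20): Tbx3 and Klf4 were lower, and Prdm14 (1.68) and Dppa3 (1.22) higher. Core pluripotency had 4 of 14 higher and 1 lower (median 0.50), with the RNA-binding protein gene Lin28a at 1.07 and the Nodal co-receptor gene Tdgf1 at -1.09. Primitive and extraembryonic endoderm genes were lower in 5 of 7 (median -0.83), among them the laminin gene Lama1 (-2.08) and the transcription factor gene Gata6 (-1.22). Imprinted genes were higher in 6 of 11 and lower in 0 (median 0.60), led by Mest (1.57), Peg3 (1.44), Impact (1.06) and Rian (1.06).

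Genes of glucose breakdown were lower in 4 of 16 and higher in 0 (median -0.25): Hk1 (-1.03), Hk2 (-1.03), Gpi1 (-0.92) and the glucose transporter gene Slc2a1 (-0.63). S phase genes were higher in 4 of 28 and lower in 0, led by Ung (1.01), and none of 26 G2 and M phase genes reached 1.5-fold. Among immediate early genes Egr1 (-1.53) and Junb (-0.80) were the 2 of 7 lower and 0 were higher. Interferon and innate immune genes were higher in 3 of 9, with the RNA sensor gene Ddx58 at 1.65 and Oasl2 at 1.44, and cholesterol biosynthesis genes in 2 of 16, among them Sqle (0.65); neither list had a lower member. ATF4 and integrated stress response genes had 3 of 19 higher and 1 lower, hyperosmotic response genes 1 of 7 higher (Akr1b3, 0.69), and p53 targets 1 of 15 lower (Pmaip1, -1.13). No member reached 1.5-fold among 13 endoplasmic reticulum chaperones, 8 heat shock genes, 16 nuclear-encoded oxidative phosphorylation genes and 13 mitochondrially encoded genes (median 0.30 for the latter). Ribosomal protein genes had 1 of 79 lower, Rpl38 (-0.61), and germline genes 2 of 7, Sycp3 (-0.84) and Stk31 (-0.72).

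Markers of other lineages gave few measurable genes. Trophoblast genes had 4 of 9 higher and 4 lower, with Hand1 at -2.61 and Tead4 at -0.91, and a median, 0.02, that turned to -0.02 when mitochondrial and ribosomal protein genes were left out of the total. Hand1 also stood in the primitive streak and mesoderm list, of which Eomes (0.63) was the other measured member. Of 5 neuroectoderm genes 1 was higher, Sox11 (2.42), and the only measured definitive endoderm gene, Trh, was at 0.40. Epithelial genes had 2 of 8 higher and 2 lower (Esrp1 1.37, Krt18 -0.72), and mesenchymal genes 1 of 4 higher and 2 lower (Fn1 0.69, Vim -1.28). Tagln, the 1 measured fibroblast gene, was at 1.90, and Tcstv3, the 1 measured gene of the cleavage-stage-like (Zscan4 and Tcstv) list, at -2.02; both lie below 20 CPM and the latter belongs to a family of near-identical copies. Without replicates these are differences between 2 libraries of unequal depth. Among barcodes with at least 1000 genes, of which ND kept 8, 0 LIF and STAT3 responsive genes and 0 naive genes counted as lower, with 5 of the 10 and 9 of the 20 members still giving a value.

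The sorbitol comparisons set cells kept in LIF at raised osmolarity for 72 h against NS. Most measured genes of the hyperosmotic response list (8 of 9, 9 of 10 and 7 of 9 at 200, 250 and 300 mM) were higher than in NS. Sgk1, a kinase gene induced by osmotic stress, went from 25.3 CPM in NS to 117, 131 and 177 CPM at 200, 250 and 300 mM (ENSMUSG00000019970; chromosome 10, 21882184 to 21999903). Slc5a3, the myo-inositol transporter gene, was at 5.78 CPM in NS and 5.45-fold, 5.41-fold and 4.68-fold higher, and Slc6a6, the taurine transporter gene, went from 54.2 to 148, 126 and 209 CPM. The naive factor genes Klf4 and Tbx3 were higher as well, with Klf4 at 344, 407 and 395 CPM against 102 in NS (log2 1.75, 1.99 and 1.95). The metallothionein genes Mt1 and Mt2, which encode metal-binding proteins, were far lower.

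Ranked by the smallest of the 3 ratios, the highest gene was Ly6a, which encodes the surface antigen Sca-1 (ENSMUSG00000075602; chromosome 15, 74994877 to 74998031). It stood at 8.39 CPM in NS and at 140, 150 and 134 CPM over the doses, 16.6-fold, 17.9-fold and 15.9-fold higher (log2 at 300 mM 3.99, 3.77 to 4.23). H19, an imprinted long non-coding RNA (ENSMUSG00000000031; chromosome 7, 142575529 to 142578143), went from 139 to 943, 794 and 932 CPM. Fxyd2, which encodes a regulator of the sodium pump (ENSMUSG00000059412; chromosome 9, 45399669 to 45410278), went from 28.8 to 178, 204 and 141 CPM. Nrk (4.59-fold to 7.02-fold), Man2a1 (4.25-fold to 4.51-fold), Tcf7l2, a Wnt pathway transcription factor (3.86-fold to 5.98-fold), Meioc (3.56-fold to 4.17-fold) and Stra8 (3.46-fold to 4.06-fold) were next, the last 2 being genes of meiotic entry. The histone gene Hist1h1c (4.02-fold to 6.13-fold) is uncertain because of its near-identical relatives.

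At the other end, Mt1 (ENSMUSG00000031765; chromosome 8, 94179082 to 94180327) went from 2287 CPM in NS to 231, 182 and 285 CPM, and Mt2 (ENSMUSG00000031762; chromosome 8, 94172664 to 94173568) from 994 to 115, 126 and 170 CPM. Lefty1, a Nodal antagonist gene, was 6.99-fold, 4.57-fold and 4.78-fold lower, and Sycp3, which encodes a protein of the synaptonemal complex, 3.83-fold, 6.43-fold and 7.56-fold lower. Gas5, a non-coding host gene of small nucleolar RNAs, went from 443 to 141, 109 and 113 CPM. Anxa2 (3.16-fold to 3.96-fold), Dhrs7 (2.97-fold to 4.38-fold) and Rhoc (2.90-fold to 3.86-fold) were also lower. Ftl1, the ferritin light chain gene (2.90-fold to 3.84-fold lower), and Hist1h2ae (3.04-fold to 7.22-fold lower) share near-identical copies and are uncertain, and the Hist1h2ae log2 ratio at 300 mM turned from -2.85 to 0.03 (-2.25 to 1.58) among the 19 barcodes of that library with at least 1000 genes.

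Scaling bears on every sorbitol ratio. With CPM the median gene of at least 5 CPM had a log2 ratio to NS of 0.20, 0.23 and 0.29 at 200, 250 and 300 mM. Median-of-ratios scaling shifted all ratios by -0.22, -0.24 and -0.26, against -0.02 for ND, so list medians or counts are given with both scalings where a median changes sign or a count moves by more than 1.5 times and more than 1 member. Of genes 2-fold apart from NS, 76.7%, 76.5% and 77.3% were higher with CPM and 51.8%, 50.9% and 50.5% with median-of-ratios scaling. In ND the share was 50.5% with CPM and 47.7% with the other scaling.

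Of the hyperosmotic response list, 8 of 9, 9 of 10 and 7 of 9 measured genes were higher at 200, 250 and 300 mM and 0 were lower. Its medians, 1.61, 1.81 and 1.87 (1.39, 1.58 and 1.61 with median-of-ratios scaling), exceeded all 10000 random lists at each dose. At 300 mM Slc6a12, the betaine transporter gene, had a log2 ratio of 4.64 (3.43 to 6.15), Sgk1 2.81, Slc5a3 2.23 and Slc6a6 1.95. Naive pluripotency genes were higher in 4, 6 and 10 of 19 and lower in 3, 0 and 0, with medians of 0.01, 0.47 and 0.59 (-0.21, 0.23 and 0.33 with the other scaling, which turned the sign at 200 mM, where 2 were then higher and 5 lower). At 300 mM they were led by Tbx3 (1.97), Klf4 (1.95), Spp1 (1.41) and Nr5a2 (0.99). LIF and STAT3 responsive genes were higher in 6, 4 and 7 of 10 and lower in 0 (medians 0.67, 0.51 and 0.74), and in 3, 1 and 4 with median-of-ratios scaling (medians 0.45, 0.27 and 0.48). After Klf4 the largest ratios at 300 mM were those of Tfcp2l1 (0.93), Klf5 (0.88) and Bcl3 (0.87). Core pluripotency genes were higher in 2, 3 and 5 of 14 and lower in 3, 1 and 0, with Sall4 at 1.95 and the methyltransferase cofactor gene Dnmt3l at 0.98, and the median at 250 mM, 0.09, turned to -0.14 with the other scaling, under which 2, 2 and 3 were higher and 5, 1 and 3 lower. Formative and primed genes were higher in 2, 3 and 3 of 9 and lower in 3, 3 and 1 (medians -0.32, -0.48 and -0.20); 5, 5 and 3 of 11 were lower when mitochondrial and ribosomal protein genes were left out of the total, and 4, 5 and 2 with median-of-ratios scaling. Within that list the de novo methyltransferase gene Dnmt3b (1.58) and Otx2 (1.53) were higher at 300 mM, and Tcf15 (-0.86) was lower.

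Primitive and extraembryonic endoderm genes were higher in 5, 7 and 7 of 8 and lower in 1 (medians 0.61, 0.89 and 1.14), or higher in 2, 4 and 6 with median-of-ratios scaling (medians 0.39, 0.65 and 0.88). Amn (1.81), the laminin gene Lamc1 (1.61) and Gata6 (1.24) led them at 300 mM. Imprinted genes were higher in 7 of 12, 7 of 13 and 8 of 13 and lower in 0 (medians 0.80, 0.88 and 0.90), or lower in 1, 1 and 2 with median-of-ratios scaling (medians 0.58, 0.65 and 0.64), led at 300 mM by the growth factor gene Igf2 (3.67), H19 (2.75), Peg10 (1.56) and Peg3 (1.55). Both measured streak and mesoderm genes, Eomes (1.70 at 300 mM) and Hand1 (1.03), were higher at every dose with CPM, but 1 of the 2 at 250 mM with median-of-ratios scaling, where Hand1 (0.68 with CPM) fell within 1.5-fold. Trophoblast genes went both ways, 4 of 9 higher at each dose and 4, 1 and 2 lower, with the cadherin gene Cdh3 at 1.92 and Id2 at -1.19. Neuroectoderm genes had 3 of 6, 2 of 5 and 1 of 4 higher and 2, 2 and 1 lower; Pax6, a transcription factor of the neural and eye lineages, was at -3.40, and the list's medians at 200 and 300 mM turned from 0.20 and 0.06 to -0.02 and -0.20 with median-of-ratios scaling. With mitochondrial and ribosomal protein genes left out of the total, 7 neuroectoderm genes reached 5 CPM at 300 mM and 4 of them were higher, 1 among those measured with CPM. No definitive endoderm gene of 1, 2 and 2 measured reached 1.5-fold. The cleavage-stage-like list had 5 of 5 members higher at 200 mM, 0 of 2 at 250 mM and 0 of 1 at 300 mM, where the 0.10 of Tcstv3 turned to -0.16 with the other scaling. Most of the 5 passed the 5 CPM minimum only through the 200 mM library, so that count largely follows from the minimum. The whole list summed to 29.8 CPM in NS and to 69.3, 41.2 and 28.8 CPM over the doses. With the total outside mitochondrial and ribosomal protein genes more members reached 5 CPM. Of these 9 of 9, 3 of 6 and 1 of 4 were higher, against 5, 0 and 0 of those measured with CPM.

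Ribosomal protein genes were lower in 4, 9 and 28 of 79 and higher in 3, 2 and 2 (medians -0.19, -0.31 and -0.44), and lower in 16, 34 and 45 with median-of-ratios scaling. At 300 mM, 624 other genes with a longest transcript no longer than the ribosomal median had a median of -0.30. By the median transcript of the gene's own type, 852 other genes no longer than the ribosomal median had a median of 0.03. Rpl28 (-1.22) and Rpl18 (-1.09) were among the lower ones at 300 mM, while the retrogene-derived Rpl10l (2.06) and Rpl39l (1.39) were higher. G2 and M phase genes were lower in 4, 3 and 6 of 26 and higher in 0 (12, 10 and 11 lower with the other scaling), with Top2a (-0.84), Mki67 (-0.78), Aurka (-0.70) and Ccnb2 (-0.69) first at 300 mM. S phase genes had 1, 2 and 5 of 28 higher and 2, 1 and 1 lower, with Ccne2 at -1.43 and Mcm2 at 0.80. Median-of-ratios scaling gave 0, 0 and 1 higher and 4, 5 and 5 lower S phase genes, and turned the medians of 0.08 and 0.09 at 250 and 300 mM to -0.16 and -0.17. Mitochondrially encoded transcripts were higher in 4, 3 and 5 of 13 and lower in 1, 0 and 1 (medians 0.13, 0.48 and 0.43, the first turning to -0.09), or higher in 2, 1 and 2 with the other scaling, with mt-Co3 at 1.09 and mt-Atp8 at -1.09. They made up 3.98% of UMIs in NS, 4.98% in ND and 5.61%, 5.78% and 6.13% in the sorbitol libraries.

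Glycolysis genes divided, 3, 2 and 4 of 16 higher and 2, 3 and 4 lower, with Gapdh at -1.30, Aldoa at -0.86, Pfkp at 1.21 and Slc2a3 at 1.06; the median at 300 mM, 0.04, turned to -0.22 with median-of-ratios scaling, with 2, 1 and 2 higher. Nuclear-encoded oxidative phosphorylation genes had 0 of 16 higher and 1, 0 and 2 lower, Ndufb8 (-0.70) and Sdhb (-0.66) at 300 mM, and the 250 mM median, 0.06, turned to -0.17, with 4, 3 and 5 lower. ATF4 and integrated stress response genes had 4, 2 and 3 of 19 higher and 7, 3 and 5 lower, with the serine synthesis gene Psat1 at 1.22 and Chac1 at -1.27, and with the other scaling 2, 0 and 2 higher and 8, 7 and 6 lower. Endoplasmic reticulum chaperones had 2, 1 and 0 of 13 higher and 1 lower (Herpud1, -0.62), with a 300 mM median of 0.09 that turned to -0.17 and 0 higher and 1, 3 and 2 lower with the other scaling. Heat shock genes had 2 of 10, 4 of 10 and 3 of 9 higher and 2, 0 and 1 lower (Hspa1b 1.87, Hsph1 1.11), and their medians at 200 and 300 mM, 0.11 and 0.10, turned to -0.11 and -0.16, with 3, 2 and 2 lower. P53 targets had 2, 2 and 4 of 15 higher and 6, 2 and 2 lower (Pmaip1 1.67, Phlda3 -1.17), and immediate early genes 2, 1 and 3 of 8 higher and 1 lower at each dose (Fos 1.23, Atf3 -1.01). The median of the p53 list at 300 mM (0.05) and those of the immediate early list at 250 and 300 mM (0.06 and 0.20) turned to -0.21, -0.17 and -0.06. That scaling gave 1, 0 and 3 higher and 6, 5 and 3 lower p53 targets, and 2, 0 and 1 higher immediate early genes.

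Cholesterol biosynthesis genes were higher in 8 of 16 at 200 mM (5 with median-of-ratios scaling) and in 2 of 16 at 250 and at 300 mM, with 0, 0 and 1 lower. Hmgcs1, an early enzyme of the pathway, was at 0.71 at 300 mM, and the medians at 250 and 300 mM, 0.08 and 0.14, turned to -0.16 and -0.12, with 2 and 5 genes lower. Interferon and innate immune genes had 4, 4 and 5 of 9 higher and 1 lower (Ddx58 1.85, Oasl2 1.71, Bst2 -1.59), or 3 higher at each dose with median-of-ratios scaling. Germline genes had 2 of 7 higher and 4, 3 and 2 lower (Dazl 2.04, Sycp3 -2.92), or 4 lower at each dose with the other scaling. Epithelial genes had 1, 1 and 2 of 8 higher and 3, 2 and 3 lower (Cdh1 1.17, Cldn4 -0.86; 4 lower at 250 mM with the other scaling), and mesenchymal genes 1, 2 and 2 of 4 higher and 1, 1 and 0 lower (the fibronectin gene Fn1 2.09, Zeb1 1.02). S100a4 of the fibroblast list was at 2.39 at 300 mM, with a level of 6.87 CPM, and 2 of 2, 1 of 1 and 2 of 2 measured members were higher. Each dose is 1 library against the same NS library, so chance values of NS enter all 3 comparisons.

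**Figure D2:**
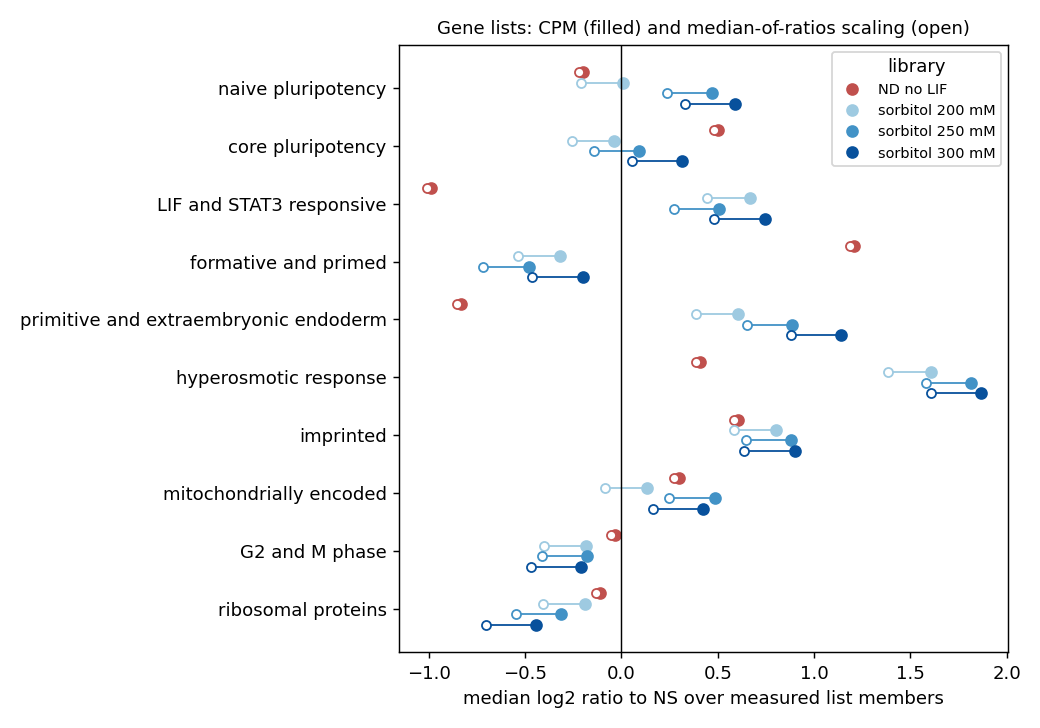
Each point is the median log2 ratio to NS of the measured members of a gene list in 1 library, filled for CPM and open for median-of-ratios scaling. Of the 10 lists drawn, hyperosmotic response genes lie highest in the sorbitol libraries (1.61, 1.81 and 1.87), LIF and STAT3 responsive genes are on opposite sides of NS in ND (-0.99) and sorbitol (0.67, 0.51 and 0.74), and with the open scaling the naive list at 200 mM (0.01 to -0.21), the core list at 250 mM (0.09 to -0.14) and the mitochondrially encoded list at 200 mM (0.13 to -0.09) change side.

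Over NS and the 3 doses, 628 of 3659 genes with at least 50 CPM were in ascending order and 160 in descending order; with median-of-ratios scaling 359 ascended and 268 descended. Ascending order was seen for 7 of 19 naive pluripotency genes and 6 of 14 core pluripotency genes, and descending order for 0 of either (5 and 3 ascending and 0 descending with the other scaling). Tbx3 went from 105 CPM in NS to 280, 326 and 411 CPM, Sgk1 and Tcf7l2 (13.2, 51.1, 53.8 and 79.1 CPM) also ascended, and Sycp3 descended through 107, 27.9, 16.6 and 14.1 CPM. Of the ribosomal protein genes 40 of 79 descended and 1 ascended, or 49 and 1 with the other scaling. Ly6a, H19 and Fxyd2 showed no order over the doses, and Zfp42 stood below NS at 200 mM. With 4 libraries no trend was tested.

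Sorbitol at 300 mM was set directly against ND, a comparison that does not pass through NS. Among the list members that differed, Klf4 stood at 395 CPM against 30.9 in ND (12.8-fold) and Tbx3 at 411 against 29.6 (13.9-fold). Lef1 was at 1.09 CPM against 41.9 (log2 -5.27, -6.41 to -4.33), and Fgf5 at 0.36 against 13.0 (log2 -5.17, -7.47 to -3.58), the latter from 3 UMIs at 300 mM. Zfp42 was 1.68-fold higher at 300 mM.

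Ly6a (25.8-fold), Hand1, a transcription factor of heart and placenta (60.2 against 4.81 CPM, 12.5-fold), Fbxo2 (9.58-fold), the Wnt receptor gene Fzd5 (9.14-fold), Fxyd2 (141 against 15.7 CPM), S100a6 (594 against 72.0 CPM, 8.25-fold), the chromatin protein gene Hmga2 (8.02-fold) and Epha4 (6.98-fold) were the other genes highest at 300 mM. The lowest were Ccnd1 (6.87 against 113 CPM, 16.4-fold lower), Cbr3 (11.3-fold), Lefty1 (14.6 against 152 CPM, 10.4-fold), the neurofilament gene Ina (8.94-fold), the hormone gene Apela (19.3 against 121 CPM, 6.26-fold), Pcbp4 (5.89-fold), Emb (5.52-fold), Mt1 (5.29-fold), Platr10 (4.88-fold) and Irf1 (4.85-fold). LIF and STAT3 responsive genes were higher in 8 of 10 and lower in 0 at each dose against ND, with medians of 1.54, 1.42 and 1.66. Formative and primed genes were lower in 9, 9 and 7 of 12 and higher in 0, 1 and 1, and naive genes higher in 7, 9 and 10 of 20 and lower in 6, 3 and 2. At 300 mM, primitive and extraembryonic endoderm genes were higher in 7 of 8 (Lama1 3.16, Amn 2.91, Gata6 2.46), hyperosmotic response genes in 8 of 9, mesenchymal genes in 3 of 4 (Vim 1.78, Fn1 1.40) and glycolysis genes in 5 of 16 (Hk1 1.67, Pfkp 1.63), against 2 of 16 lower. Ribosomal protein genes were lower in 14 of 79 and imprinted genes higher in 6 of 13 and lower in 3, where Igf2 was at 4.94 and the list median, 0.10, turned to -0.14 with median-of-ratios scaling. That scaling shifted this comparison by -0.24, took the share of higher genes among those 2-fold apart from 74.7% to 52.3% and the count of lower ribosomal protein genes to 38, of lower core pluripotency genes from 3 to 5 and of lower naive genes to 4. Among barcodes with at least 1000 genes, 4 naive genes counted as higher and 0 formative genes as lower, with 7 and 0 members giving a value.

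The log2 ratios to NS of ND and of each dose were then compared across 3791 genes with at least 50 CPM in any library, genes not being independent replicates. Pearson's r was 0.20, 0.26 and 0.29 at 200, 250 and 300 mM. Unchanged libraries simulated from the NS profile, with 1 simulated control shared by both ratios, gave 0.28, 0.28 and 0.27. These lay above the observed value at 200 and 250 mM and below it at 300 mM. A simulated r comes only from counting error and the shared control, so it is set by the depths. It therefore does not decide how alike the observed ratios are. With minimums of 10 and 200 CPM the simulated value lay above the observed one at 300 mM too (0.267 against 0.246, and 0.277 against 0.275). The covariance was 0.048, 0.058 and 0.078, against 0.0014 for each of the simulated sets, differences of 0.047, 0.057 and 0.076. With NS barcodes split into 2 random sets, 1 for each comparison, r was 0.20, 0.25 and 0.29. At 300 mM, 129 genes were 1.5-fold higher than NS in both libraries, where independent lists would share 67.6, and 52 were lower in both, against 15.6; part of the excess may come from the shared NS library. At 200 and 250 mM, 90 and 101 were higher in both, against 46.1 and 49.7, and 49 and 50 lower in both, against 17.2 and 11.6. Genes lower in ND and higher in sorbitol numbered 33, 34 and 38 over the doses, against 25.4, 27.4 and 37.3, and genes higher in ND and lower in sorbitol 25, 21 and 20, against 31.1, 21.0 and 28.4. Klf4, Tbx3 and S100a6 were on opposite sides of NS in ND and sorbitol, whereas Anxa2 and Dhrs7 were lower in both. Across 2366 genes, the correlation of log2 CPM was 0.974 between ND and NS and 0.983 to 0.986 among the sorbitol libraries. Between sorbitol and NS it was 0.938, 0.942 and 0.919 at 200, 250 and 300 mM. Between sorbitol and ND it was 0.933, 0.941 and 0.925.

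Single barcodes were compared after thinning each to 500 UMIs. Zfp42 gave a UMI in 24.5% of NS barcodes (23.6 to 25.3, exact binomial), 22.9% in ND (22.0 to 23.7) and 22.6%, 31.5% and 35.6% in the sorbitol libraries. Without thinning the shares were 69.2%, 35.2%, 36.9%, 51.6% and 51.4%, so that NS, the deepest library, stood highest. If every barcode of a library drew from 1 shared profile the thinned shares would be 24.5%, 23.1%, 23.1%, 32.2% and 35.7%. No barcodes of a cell type without Zfp42 were at hand to measure free RNA. H19 differed further from a shared profile in the sorbitol libraries. After thinning it gave a UMI in 26.5%, 20.6% and 25.6% of their barcodes, where a shared profile would give 37.3%, 33.1% and 38.0%.

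**Figure D3:**
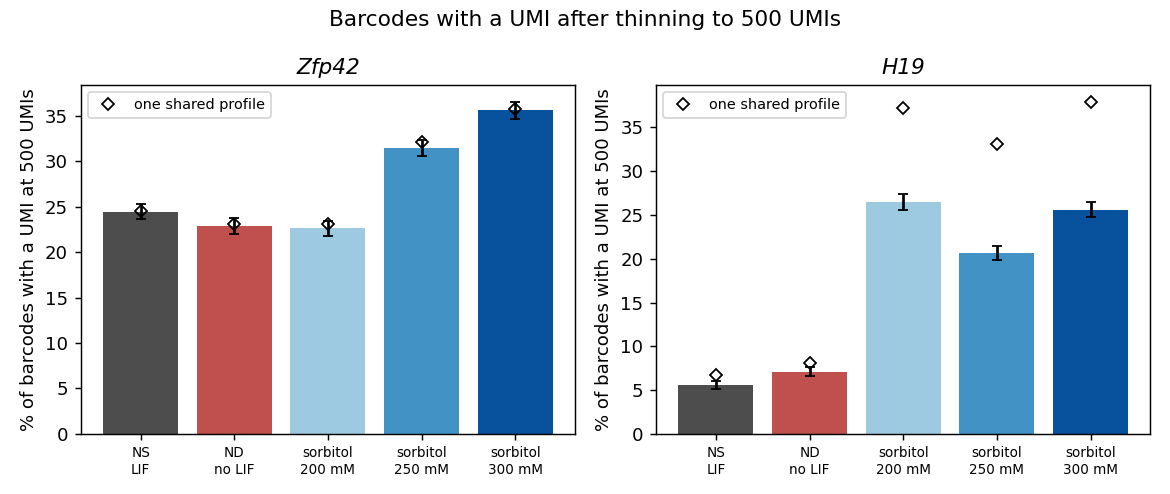
Bars give the percentage of barcodes with a Zfp42 or H19 UMI after thinning to 500 UMIs, with exact binomial 95% intervals, and diamonds the percentage a single shared profile would give. Zfp42 bars, from 22.6% to 35.6%, lie close to the diamonds, from 23.1% to 35.7%, while the H19 bars of the sorbitol libraries (26.5%, 20.6% and 25.6%) lie below theirs. Closeness to the diamonds does not exclude barcodes that lack Zfp42.

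With 3000 barcodes per library, the 3 largest clusters parted NS, ND and the sorbitol libraries, which shared 1 cluster. It held 96.9%, 97.1% and 99.3% of sorbitol barcodes, another 90.9% of NS barcodes and a further one 84.5% of ND barcodes, so these clusters may be the libraries and no shares of cell types are drawn from them. The smallest cluster, of 99 barcodes, drew on all 5 libraries, with 15 from NS, 4 from ND and 44, 21 and 15 from the sorbitol libraries. In it 3 markers of the cleavage-stage-like set were detected and the set as a whole was 5.27 higher on the log2 scale than in other barcodes, but no marker stood among its 10 leading genes and it was left unnamed. Among marker sets, at least 3 primitive endoderm genes were detected in 7 NS, 4 ND and 28, 52 and 62 sorbitol barcodes, where a shared profile would give 2.30, 0.45, 6.45, 11.5 and 16.3. At least 2 genes of the cleavage-stage-like set were detected in 9 NS, 2 ND and 16, 9 and 3 sorbitol barcodes, against 0.35, 0.00, 1.80, 0.70 and 0.20. At least 2 fibroblast genes were detected in 1 ND barcode and in 0 of 10000 NS barcodes. For NS this allows up to 0.03% of barcodes with UMIs of 2 such genes at a floor of 3 counts. The exact binomial upper limit is 0.0369%. Neither sets a limit on fibroblasts, and 1 such gene or more was seen in 41 NS barcodes.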

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

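All alternatives reported here were planned; the rule that withholds ratios near the floor was set after the values were seen. No paired analysis was possible because each condition has 1 library and no test between groups was run. Of 15 lead results (Zfp42 ratios and list counts), all 15 stayed without a barcode filter, at 10% mitochondrial UMIs, without the 5% of barcodes with most UMIs and with equal weights. Among other results 389, 391, 384 and 387 stayed and 2, 0, 7 and 4 moved under those 4 settings. With at least 1000 genes per barcode, which leaves 9255 NS, 8 ND and 22, 47 and 19 sorbitol barcodes, 138 other results stayed, 216 moved and 3 reversed. There the Zfp42 log2 ratio was 0.17 at 200 mM (reversed) and 0.47 (-0.13 to 1.02) at 300 mM, and Pou5f1 at 200 mM was 0.068, Sox2 in ND -0.17 and Hist1h2ae at 300 mM 0.028 (all reversed). Naive genes counted as lower were 0 in ND, 1 at 200 mM and 1 at 250 mM; LIF and STAT3 responsive genes lower in ND were 0, formative genes lower at 300 mM against ND 0 and naive genes higher there 4. Few barcodes leave few UMIs per gene, and intervals that span 0 for these genes show that depth limits this setting. Median-of-ratios scaling left 10 lead and 239 other results, moved 5 and 151, and reversed Nanog at 300 mM (-0.15). Its Zfp42 ratios were -0.33, 0.23 and 0.39 over the doses, with naive genes lower in 5 at 200 mM and 1 at 250 mM; by construction it shifts all genes of a library alike. CPM outside mitochondrial and ribosomal protein genes moved 3 lead and 53 other results, with Zfp42 at 0.39 and 0.55 at 250 and 300 mM and 1 naive gene lower at 250 mM; besides a shift of all ratios of a library, it lets more members reach 5 CPM. A 2-fold limit left 0 naive genes lower at 200 mM. A minimum of 10 CPM gave correlations of ND and sorbitol ratios of 0.165, 0.216 and 0.246, and the cause was not tested. Simulated unchanged libraries gave 0.278, 0.289 and 0.267 at that minimum, values set by the depths and the shared control, which do not decide likeness. The covariances there were 0.052, 0.065 and 0.085, against 0.0053, 0.0054 and 0.0053 when simulated. With split NS barcodes r was 0.144, 0.193 and 0.225. Shares of barcodes with a Zfp42 UMI were 13.2%, 12.4%, 12.8%, 17.3% and 19.6% at 250 UMIs and 69.2%, 35.2%, 36.9%, 51.6% and 51.4% without thinning, as the depth per barcode sets. At Leiden resolution 1.0 the cluster with most NS barcodes held 88.6% of NS and 11.9% of ND barcodes. In place of the sorbitol cluster 3 clusters held 21.0%, 47.0% and 18.3% of barcodes at 200 mM, 38.2%, 33.0% and 18.1% at 250 mM and 36.6%, 13.6% and 41.2% at 300 mM. A cluster of 524 barcodes led by Krt8 and H19 held 0.67% of NS, 0.10% of ND and 5.23%, 5.50% and 5.97% of sorbitol barcodes, and another of 422, with 6 cleavage-stage-like markers detected, 0.93%, 0.23%, 7.23%, 3.23% and 2.43%; the cause was not tested. Clusters with at least 1000 genes per barcode were not run, since too few barcodes were left.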

Other observations

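The tests of free RNA and of depth, for the few genes that varied strongly between barcodes, were chosen only after the result was seen. So were those of matched length, of abundance as the whole source, of scaling, of doublets of deep cells and of extraembryonic-like genes. The others were written down before. Some barcodes of the sorbitol libraries held many H19 UMIs. At least 3 H19 UMIs among 500 were found in 476, 445 and 523 barcodes at 200, 250 and 300 mM (4.77%, 4.45% and 5.31%), where a shared profile would give 119, 80.05 and 125. NS and ND also exceeded a shared profile, with 32 and 24 such barcodes against 0.53 and 0.86. Compared with barcodes without H19, the keratin gene Krt8 was 7.48-fold, 30.4-fold and 12.7-fold higher in them, Hand1 4.16-fold, 6.35-fold and 5.57-fold, and Igf2 5.22-fold, 9.96-fold and 7.29-fold, while Zfp42 was at 0.75, 0.58 and 0.70 of its level. These genes were chosen after their values were seen.

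Collagen genes (Col1a1, Col1a2 and Col3a1) argued against feeder fibroblasts as most of the H19-rich barcodes, as their sum was at most 13.66 CPM in them. The sums were 4.54, 2.30 and 13.66 CPM at 200, 250 and 300 mM, from 2, 1 and 6 UMIs. In barcodes without H19 they were 2.81, 1.42 and 2.11 CPM. A few fibroblasts among the H19-rich barcodes stay open. At most 0.84% (upper limit 2.14%) of the H19-rich barcodes held 2 times the UMIs of the shallowest barcode. Doublets of cells as deep as those kept would do so if UMIs add up. Among all barcodes the share was 0.55%, 0.55% and 0.73% at 200, 250 and 300 mM. The narrow slice of depths thus fixed this outcome for any barcodes, and it tells nothing particular about the H19-rich ones. Doublets of shallower cells stay open: the median UMI number was at most 1.009 times that of barcodes without H19, but the bound of 1.1 set beforehand was wrong, as depths begin abruptly (5th percentile at most 1.011 times the lowest) and such doublets need not be deeper than single cells; this was judged after the values were seen. Krt8, Krt18, Hand1, Col4a1 and Col4a2 together were 3.20-fold, 7.30-fold and 4.65-fold higher in the sorbitol libraries, 7.51-fold in NS and 6.98-fold in ND, but they were picked from the pattern and decide nothing. Without them the fixed trophoblast list was 1.57-fold, 2.86-fold and 2.06-fold higher and the primitive and extraembryonic endoderm list at 1.13, 0.89 and 1.11 of its level (with them 2.63, 5.94 and 3.81, and 1.28, 1.22 and 1.296), with naive genes at 0.85, 0.71 and 0.80, so extraembryonic-like cells stay open.

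Ribosomal protein transcripts were lower at 300 mM sorbitol, with a median log2 ratio to NS of -0.44. The highest median under 3 other scalings was -0.44 and the lowest -0.70. The highest came from equal weight for each barcode, which still scales to a total. The other 2 scalings shift all ratios of a library alike, so the 3 do not decide whether scaling to CPM lowers them. The median gene of at least 5 CPM stood at 0.29 with CPM, and such a shift leaves the gap to it unchanged. Poorer recovery of short transcripts stays open, as the 2 measures of length differ. The 4319 other genes within the ribosomal range of longest transcripts (562 to 3008 nt) had a median of 0.06, too wide a set for the bound set beforehand. The 624 no longer than the ribosomal median of 1094 nt had -0.30. By the median transcript of the gene's own type, the 852 no longer than the ribosomal median of 711.5 nt had 0.03. Genes nearest in length to each ribosomal gene had a median of -0.20 by longest transcript and -0.02 by the median transcript of the gene's own type, and across genes the ratio went with length (Spearman's rho 0.31 and 0.27; genes are not independent replicates). Other genes as abundant in NS had a median of -0.25 (199 genes), so a loss shared by all abundant transcripts may be part of the pattern and stays open. The ribosomal median, -0.442, lay below all random lists matched on expression (95% of them from -0.25 to 0.03). Those lists were matched only within broad groups of mean expression, so they do not decide whether such a loss was the whole source. A response to sorbitol was not tested apart from the library and stays open too.

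Within a library, few genes varied strongly between barcodes at 500 UMIs: of 3430 genes in NS, 3 had a dispersion over 1.5 times that of a single shared profile. A simulated gene at 0.44 UMIs, lacking in 20% of barcodes, had a dispersion of 1.12 and would not pass that cut. The count therefore does not show that barcodes differ little. That the barcodes hold only free RNA, spread evenly over all droplets as 1 profile, was argued against by mitochondrially encoded UMIs. Their dispersion was 1.535 in the lowest library and 2.087 in the highest. This bears on an even spread only, and free RNA spread unevenly over droplets stays open. Too few UMIs per barcode may account for part of the small number of genes past the cut, as 26 genes of NS passed 1.5 without thinning. Uniform cells were not tested as an explanation.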
